A study of Homo sapiens with 4 samples.

How the data were processed

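RNA bound by ADAR1, an enzyme that turns adenosine into inosine in double-stranded RNA, was mapped by individual-nucleotide crosslinking and immunoprecipitation (iCLIP). The cells were H9, an established human embryonic stem cell line, in which ADAR1 had been knocked down and either Flag-tagged ADAR1 or a Flag-tagged mutant, E912A, had been put back with a virus. E912A replaces a glutamate of the catalytic site and leaves the protein without deaminase activity. Per the labels' protocols, cells were irradiated with UV light at 400 mJ/cm2, the protein was pulled down with 8 µg of anti-Flag antibody, bound RNA was trimmed with micrococcal nuclease for 5 min, and cDNA was circularised, amplified and sequenced. In iCLIP, reverse transcription tends to stop next to the crosslinked base, so a position in the RNA stands for a contact with the protein.

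The series has 4 samples, 2 technical replicates of each construct. Per the labels, both replicates of a construct share 1 deposited list, so the replicates could not be compared and no value has a replicate error. The labels give both Flag-ADAR1 replicates the same barcode sequence and the mutant replicates different ones. Whether this is a slip in the labels or means a single Flag-ADAR1 library could not be told. Each list holds single positions of 1 bp with a strand, a label made of an Ensembl transcript identifier with an intron tag where the position is intronic, and a score. The score is the authors' value, a whole number of 2 or more in both deposited lists. What it counts, how positions were called and which threshold was used are not given in the sources used here. The tags of the labels were taken as they stand: a label without the intron tag is called an exon label. TopHat2 2.0.9 and the builds GRCh37 and hg19 are named per the submitters' processing notes. Coordinates below are hg19 and count from 1. Read totals were not given, so the depth of each library is unknown. The score was used to describe and rank positions within a list. Counts at a score minimum, shares of the summed score and score correlations were also set side by side between the lists, where the scale may differ with depth.

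Transcript identifiers were matched without their version to GENCODE release 29, which supplied gene names, gene types, gene spans and transcript sequences. That release is on GRCh38, so none of its coordinates were set against the lists. Of the distinct transcript labels, 14365 of 15824 in the Flag-ADAR1 list and 17184 of 18975 in the mutant list were matched. Unmatched labels held 11.6% and 10.7% of the positions. With no annotation of hg19, shares per coding region or untranslated region, windows around microRNA hairpins, random placement at hairpins and repeat content at positions were not analysed here. Beside the exon and intron labels, microRNA genes named by a label were counted in place of hairpins. Of 99.8% of the matched positions in both lists, the strand was that of the gene.

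A position was called shared when the other list held the same base on the same strand. Chance overlap was described with 100 random placements of the other list over the same chromosome and strand, or within 10 kb of each position. Neighbouring positions often formed runs, so positions within 5 bp on the same strand were also merged into sites. This was chosen after the gaps between positions had been seen. Shares have exact (Clopper-Pearson) 95% binomial intervals, and ratios of shares between lists have exact conditional 95% intervals. These intervals cover counting error only, and they are too narrow because neighbouring positions are not independent. With 1 list per construct, no test between constructs was made, and where the closing section gives a ratio between the lists, its interval from resampling genes describes these 2 lists only.

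Gene lists and the rule for naming genes were fixed before the data were examined. For each list, the 10 protein-coding and 5 noncoding genes with the most positions were named, and for the comparison the 5 genes with the largest ratio of shares in each direction, among genes with at least 20 positions in both lists together, with 0.5 added to each count. From each fixed gene list, 2 to 4 members with the most positions were named. The core pluripotency factors, DROSHA, DGCR8, DICER1, ADAR and host genes of microRNAs were named outside this rule, for their part in the question. Of the genes this rule names, 2 are not reported here, though they remain in the counts. The number of members with a position was set beside 10000 random lists of the same size, matched on gene type and on 10 bins of gene span. The percentile describes these 2 lists. Expression was not measured here, so random lists were not matched on it. Of the planned microRNA hairpin rule only the labelled microRNA genes remained.

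For the closing section, the longest protein-coding transcript of each gene was searched for 13-base words of an AluY consensus in both directions. A transcript with at least 15 such words in a direction was called Alu-bearing in it. On 300 simulated copies per setting, the search recovered 100% of copies at 5% and at 10% divergence and 88.3% at 15%. Odds ratios were stratified by 10 bins of transcript length, with intervals from resampling genes and a two-sided permutation test of 10000 draws. The overlap, merging, list and word searches were first tested on simulated data. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.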

Results

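The data are 2 lists of crosslink positions, 1 for Flag-ADAR1 and 1 for the catalytic mutant Flag-ADAR1-E912A, both from H9 embryonic stem cells depleted of their own ADAR1. Each list stands for 2 technical replicates that the deposited values do not separate. The Flag-ADAR1 list held 62093 positions with a summed score of 638469, and the mutant list held 106649 positions with a summed score of 845733. The series title links ADAR1 to microRNA processing and to neural induction without its catalytic activity. The comparison therefore asks whether the mutant touched the same RNAs as the active protein, and whether microRNAs were among them. Values come without replicate error, and the intervals cover counting error only.

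By number of positions, protein-coding transcripts came first for both proteins and carried 71.3% of the Flag-ADAR1 positions (95% interval 70.9 to 71.6) and 72.8% of the mutant positions (72.5 to 73.1). Antisense RNAs followed with 6.14% and 6.23%, and long intergenic noncoding RNAs with 5.03% and 4.92%. Exon labels made up 41.3% of the Flag-ADAR1 positions (40.9 to 41.7) and 42.1% of the mutant positions (41.8 to 42.4), and the rest had intron labels. By score the picture was different. Protein-coding transcripts took 45.7% of the summed score for Flag-ADAR1 and 52.8% for the mutant, and labels without a match in the annotation took 38.1% and 30.2%. An unplaced contig of hg19, gl000220, known to carry a ribosomal RNA gene unit, held 1538 and 1645 positions, or 2.48% and 1.54% of each list, but 31% and 22.6% of the summed score. The highest score was 442 for Flag-ADAR1 and 419 for the mutant, against medians of 5 and 4. Adjacent positions had equal scores in 57.0% and 63.6% of pairs, so a summed score can count the same signal at each position of a run. Small nuclear RNAs took 1.2% of the Flag-ADAR1 score and 0.574% of the mutant score, and small nucleolar RNAs took 1.1% and 0.999%. By summed score, exon labels reached 63.7% and 60.9%.

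The mutant list was 1.72 times as long as the Flag-ADAR1 list. Runs of neighbouring positions accounted for part of this, since merging positions within 5 bp left 36748 sites for Flag-ADAR1 and 52262 for the mutant, a ratio of 1.42. A site held 1.69 positions on average for Flag-ADAR1 and 2.04 for the mutant. At scores of 10 or more, the lists were closer in size, with 12599 and 14378 positions. Both Flag-ADAR1 replicates carry the same barcode in the labels, so whether each list rests on the same number of libraries is unclear. Read totals were not given, so a difference in depth between the lists was not separated from a difference in binding.

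The mutant was listed at many of the same bases as the active protein. The lists shared 12317 positions, which were 19.8% of the Flag-ADAR1 positions (19.5 to 20.2) and 11.5% of the mutant positions (11.4 to 11.7). Random placement over the chromosome gave 0.0875% and 0.0525%, and placement within 10 kb gave 0.249% and 0.147%. Within 100 bp the shares were 60.3% and 55.3%, against 13.8% and 8.51% for placement within 10 kb. The number of pairs was highest at an offset of 0. Of the Flag-ADAR1 positions with exon labels, 26.4% (25.9 to 27.0) were also in the mutant list, against 15.2% (14.8 to 15.6) of those with intron labels. These 2 shares were not matched on score. At scores of 50 or more, 69.6% of Flag-ADAR1 positions were shared, against 16.9% at 2 to 4 and 14.3% at 5 to 9. For the mutant it was 67.0% at 50 or more and 4.66% at 2 to 4. Of the 2118 Flag-ADAR1 positions with a score of 50 or more, 1513 lay on gl000220. On the ribosomal contig, 67.0% (64.6 to 69.4) of the Flag-ADAR1 positions were in the mutant list. Positions are dense there, with 1096 mutant positions of a single transcript label between 113351 and 118399. The chance values above are for whole lists and do not apply to this contig, for which no expectation was calculated. Across all shared positions the scores had a Spearman correlation of 0.691, and it was 0.593 on the placed chromosomes alone. These are correlations across positions, which are not independent replicates, and the score is the authors' own.

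**Figure D1:**
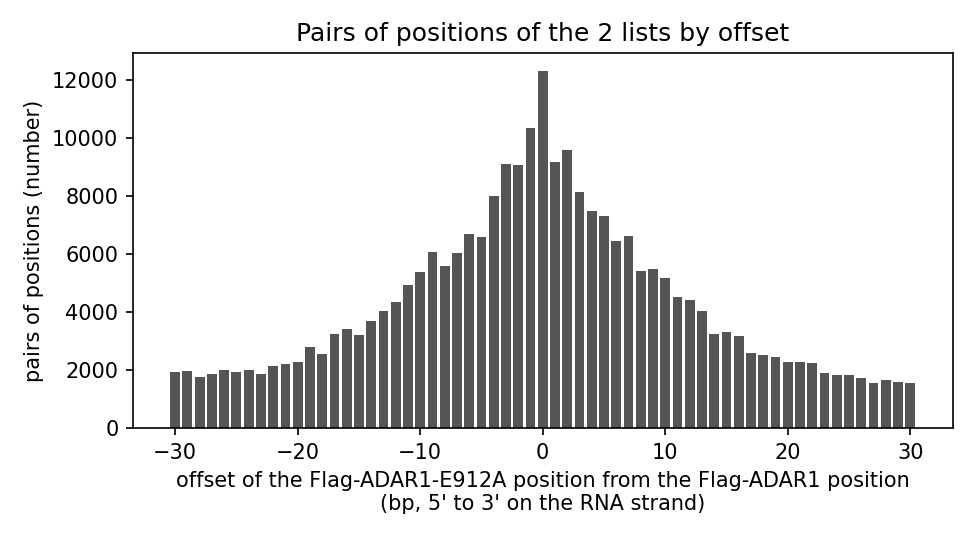
Number of pairs of positions, 1 from each list on the same strand, by the offset in bp of the Flag-ADAR1-E912A position from the Flag-ADAR1 position, counted 5' to 3' along the RNA. The bar at 0 is the highest, with 12317 pairs, and the counts fall on both sides.

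Of the 10 protein-coding genes with the most positions for each protein, 6 were the same, and most of their positions lay in introns. ANKRD30BL led the Flag-ADAR1 list with 161 positions and had 169 in the mutant list, of which 156 and 160 were intronic. KCNQ1, a potassium channel gene, led the mutant list with 175 positions and had 79 for Flag-ADAR1, all intronic. HFM1, a DNA helicase of meiosis, had 99 and 120 positions, all within 1 intronic stretch of chromosome 1 from 91852814 to 91853460. SLCO5A1 had 88 and 121, AL138752.2 had 75 and 120, and MORC4 had 69 and 102. Also among the leading genes for Flag-ADAR1 were CROCC with 83 and 71, PDE3A with 71 and 66, and the ryanodine receptor RYR2 with 63 and 75. The mutant list further had TBC1D8B with 126 positions against 46, TMEM45A with 103 against 55, HERC4 with 94 against 49, and the zinc finger gene ZNF793 with 88 against 22. ZNF793 differed from the rest in that 63 of the 88 and 16 of the 22 positions were exonic. Without runs that recur elsewhere with the same spacing and scores, CROCC fell to 43 Flag-ADAR1 positions and TBC1D8B to 86 mutant positions. All these counts follow the labels, and reads from similar sequence elsewhere in the genome were not excluded for any of these genes.

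Among noncoding genes, SNHG14, the long imprinted host transcript of snoRNAs on chromosome 15, led both lists with 118 and 167 positions. Another imprinted transcript, KCNQ1OT1, which runs antisense within KCNQ1, had 44 and 109 positions, all with exon labels. The mitochondrial large ribosomal RNA MT-RNR2 had 78 and 67, and the nuclear architectural RNA NEAT1 had 58 and 66. FTX had 56 and 74, MIR663AHG had 56 and 79, TSIX had 52 and 88, XACT had 50 and 83, and TRAF3IP2-AS1 had 39 and 84.

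Across all genes, 11640 had at least 1 Flag-ADAR1 position, 13187 had a mutant position and 9284 had both. Independent lists of these sizes would share 2613 genes, or 5996 when drawn within bins of gene span. Of 19951 protein-coding genes, 9152 and 10523 had a position, and 7571 had both, against 5833 within bins of span. The number of positions per gene had a Spearman correlation of 0.543 between the lists, across 7372 genes with at least 5 positions in both lists together. Choosing genes by the sum of both counts can itself lower this value. Genes are not independent replicates here either. Neither these draws nor the random placements of positions were matched on expression, so the set of transcripts present in the cells can raise the overlap. The series holds no control pull-down to set beside it.

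Some genes took a different share of each list. Of 2280 genes with at least 20 positions, the interval of the share ratio lay above 1, towards the mutant, for 182 and below 1 for 166, while 1932 held 1. Some intervals lie outside 1 by counting error alone, and how many was not calculated. The genes furthest towards the mutant had no listed Flag-ADAR1 position. ZFP30 had 28 mutant positions, MIR4432HG had 25, and AC040162.1, MS4A10 and ZNF208 had 23 each. The lower bound of the ratio was 4.13 for ZFP30 and 3.35 for the last 3. The genes furthest in each direction were picked by this same ratio, so their intervals do not test a difference. In MIR4432HG all 25 lay within chromosome 2 from 60616208 to 60616328, and in MS4A10 all were exonic. Towards Flag-ADAR1, BUB1B-PAK6 and FOXL2NB each had 17 positions against 4, a share ratio of mutant to Flag-ADAR1 of 0.137 (0.0335 to 0.420). MVB12B had 27 against 8, RNF212 had 16 against 5, and LIMD1 had 18 against 6. Counted as merged sites, BUB1B-PAK6 had 1 in each list, so its difference lay in the width of 1 run. FOXL2NB and MVB12B each had 4 sites against 2, RNF212 had 9 against 3, and LIMD1 had 10 against 6. Leading genes also differed in share: the ratio was 2.33 for ZNF793 (1.45 to 3.90), 1.59 for TBC1D8B (1.13 to 2.29), 0.611 for ANKRD30BL (0.490 to 0.763) and 0.498 for CROCC (0.358 to 0.692). Without recurring runs in either list the ratio for TBC1D8B was 1.11 (0.764 to 1.62), so its difference did not hold, while those of the other 3 stayed on the same side of 1. Positions come in runs, so single runs can set such ratios.

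Messenger RNAs known for inverted Alu repeats in the 3' untranslated region, the usual double-stranded substrates of ADAR1, were listed for both proteins. All 13 of them had positions in both lists, against a median of 7 in random lists for Flag-ADAR1 and of 8 for the mutant. This number lay at percentile 100 and percentile 99.9 of the random lists. XIAP, an inhibitor of apoptosis, had 21 and 60 positions, MDM4, a regulator of p53, had 38 and 44, and PAICS, a purine synthesis enzyme, had 19 and 25. In these 3 genes exon labels held 18 and 55, 37 and 43, and 19 and 22 of the positions. By number, 11 of the 13 genes had more positions in the mutant list, and as a share of each list 7 of the 13 did.

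**Figure D2:**
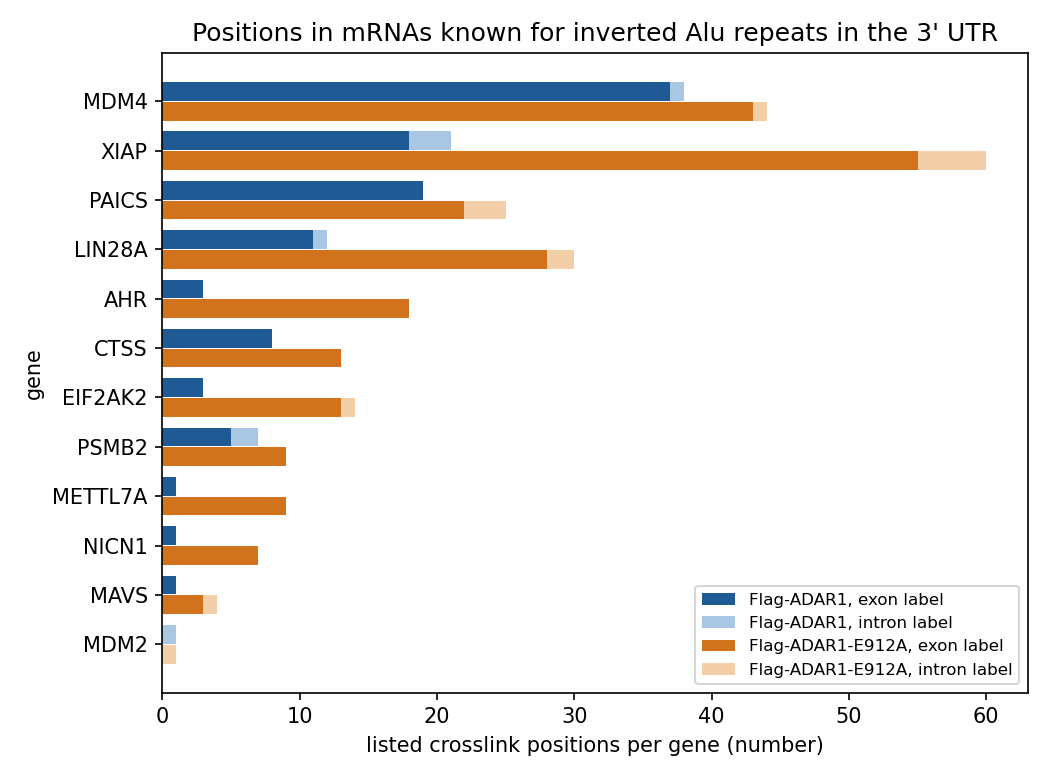
Number of listed positions in each of 12 genes whose mRNAs are known for inverted Alu repeats, with Flag-ADAR1 in blue and Flag-ADAR1-E912A in orange. Dark bars are exon labels and light bars are intron labels. Most of these genes have mainly exon labels, as in XIAP with 18 and 55 exonic positions.

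Pluripotency genes also carried positions more often than random lists. Of 22 genes, 17 had a position in each list, 15 of them in both, at percentile 99.995 for Flag-ADAR1 and 99.97 for the mutant. The fibroblast growth factor receptor FGFR1 had 27 and 43 positions, the embryonic stem cell transcript ESRG had 20 and 32, and LIN28A, which blocks let-7 maturation, had 12 and 30. LIN28A was also in the inverted Alu list, and 11 and 28 of its positions were exonic. PODXL had 7 and 21. Of the core factors, which fall outside the naming rule, POU5F1 went the other way with 13 and 7 positions, 11 and 6 of them intronic, a share ratio of 0.314 (0.106 to 0.845). NANOG had 7 and 11, all exonic, and no position was listed for SOX2. Neural induction genes stood near the middle of the random lists, with 10 and 12 of 20 genes (percentiles 59.6 and 75.6). Among them the cadherin CDH2 had 6 and 16 positions, the homeobox gene MEIS1 had 9 and 9, and doublecortin, DCX, had 4 and 11. Markers of feeder or differentiated cells had few positions. Of 13 matched genes 4 and 7 had one, at percentiles 43.2 and 85.7, and the highest were GATA6 with 1 and 3 and KRT18 with 1 and 2.

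Abundant mRNAs lay above the random lists too, with 17 and 19 of 20 genes at percentile 100 in both lists. The elongation factor EEF1A1 had 11 and 16 positions, YWHAE had 8 and 14, and beta-actin, ACTB, had 4 and 14. Abundant noncoding RNAs had 12 and 11 of 20 genes, also at percentile 100. Their random lists drew on all types other than protein-coding and microRNA genes together, pseudogenes included. The U3 snoRNA gene SNORD3A had 29 and 38 positions, RMRP had 13 and 19, and MALAT1 had 12 and 15. As random lists were not matched on expression, a high percentile in any list can include the level of its transcripts.

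Genes with known recoding sites of RNA editing were not apart from random lists of the same gene span. Positions were listed in 16 of 20 for each protein, at percentiles 89.3 and 72.6. These are long genes, and without matching on span the percentiles were 99.9 and 99.4. The glutamate receptor GRIK2 had 6 and 14 positions, the antizyme inhibitor AZIN1 had 4 and 16, and GABRA3 had 6 and 10. Genes of the response to double-stranded RNA had 8 and 11 of 15 members with a position, at percentiles 73.3 and 94.7. OAS3 had 20 and 14 positions, IFIT3 had 6 and 13, and the kinase EIF2AK2 had 3 and 14, of which 3 and 13 were exonic. With at least 3 positions per gene, this list reached percentile 98.7 for Flag-ADAR1.

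**Figure D3:**
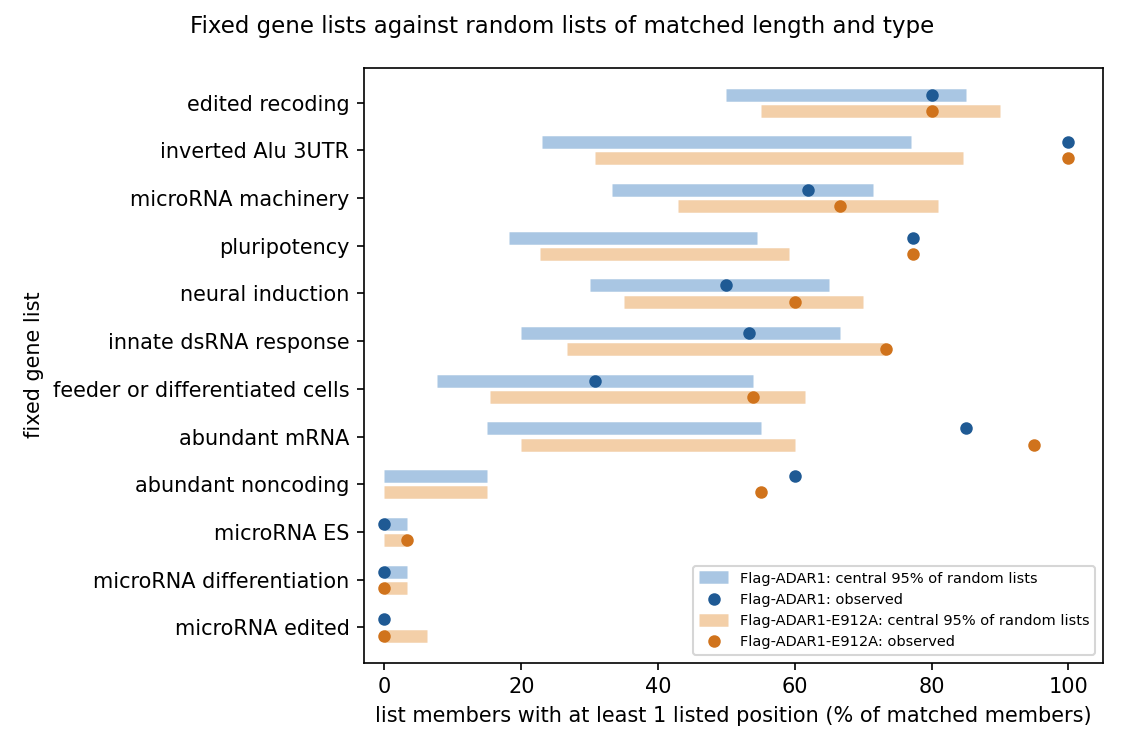
Share of the matched members of each fixed gene list with at least 1 position, in percent, for Flag-ADAR1 in blue and Flag-ADAR1-E912A in orange. Points are the observed shares and bars span the central 95% of 10000 random lists matched on gene type and span; the points of the inverted Alu, pluripotency and both abundant RNA lists lie above their bars.

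Few positions carried the name of a microRNA gene. Of 1879 annotated microRNA genes, 5 were named in the Flag-ADAR1 list with 39 positions and 8 in the mutant list with 54, and all 5 were among the 8. The ribosomal DNA microRNA annotations MIR3648-2 and MIR3687-2 held most of them, with 28 and 28 positions and with 7 and 15 positions, on chromosome 21 between 9825853 and 9826236. MIR1260A and MIR1260B had 1 and 3 positions each, with summed scores of 12 and 207 and of 18 and 213. In the mutant list the 3 positions of each gene had equal scores, so the sums can count the same signal more than once. Their spacing was the same in both genes, with scores of 69 in MIR1260A and 71 in MIR1260B. The same reads placed at both genes could give this, which was not tested. MIR5100 had 2 and 1. The mutant list alone named MIR19B2 with 2 positions, MIR515-1 with 1 and MIR515-2 with 1, the last 2 with a score of 7 each. Equal scores in that pair could likewise come from the same reads, so the 8 genes may not be separate hits.

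The microRNAs of embryonic stem cells, of differentiation and of known editing were almost absent from the labels. Of 31 stem cell microRNA genes, which include the MIR302 and MIR17 clusters, 0 were named for Flag-ADAR1 and 1, MIR515-1, for the mutant. Of 31 differentiation microRNA genes, among them the let-7 family, and of 16 edited microRNA genes, 0 were named in either list. Random lists of microRNA genes had a median of 0 as well, so the lists did not separate these microRNAs from others. Each position carries 1 label, so a position inside a host transcript can be named for the host and not for its microRNA. Among 62 host genes named for their microRNA, 20 had a Flag-ADAR1 position, 26 had a mutant position and 16 had both. MIR663AHG had the most, MIR4435-2HG had 25 and 50, MIR17HG had 6 and 7, and MIRLET7BHG had 1 and 16.

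Transcripts of the microRNA machinery were not apart from random lists, with 13 and 14 of 21 genes at percentiles 79.6 and 71.8. TNRC6B, a partner of Argonaute, had 17 and 32 positions, AGO4 had 12 and 16, and TNRC6A had 12 and 14. The nuclear processing genes DROSHA and DGCR8 had 0 and 2 each, and DICER1 had 3 and 3. The knocked-down gene itself, ADAR, had 2 intronic positions for Flag-ADAR1 and none listed for the mutant. Crosslink positions do not measure expression, so these values do not check the knockdown or the construct labels.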

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

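Each list pools its replicates, so leaving out a replicate was not possible. No paired analysis was possible because each construct has 1 pooled list, although the labels share replicate numbers. Also not run were the alternatives on cluster width and on reciprocal overlap, which are void for positions of 1 bp, and those on feature priority, base share, hairpin windows, strand of features, hairpins and genes, and repeat content, which need an annotation of hg19. Merging within 5 bp, the score minimum of 10, sites, exclusion of contigs or recurring runs, and shares of the score were added after the data had been seen. Of 179 alternatives, 128 kept their value within its interval, within 1.5 times or on the same side of the random lists or of 1. Some of the 128 could not move. Thinning left the Flag-ADAR1 list whole, so its own gene counts stayed the same, and genes with no recurring runs kept their positions. Without recurring runs the intervals of the share ratios changed for 4 named genes: those of TBC1D8B and KCNQ1OT1 came to hold 1, with ratios of 1.11 and 1.4, and those of SNHG14 and FTX came to lie below 1, with 0.617 and 0.602. Of 60 alternatives for gene lists, 3 left the central 95% of random lists: editing targets without span matching (percentiles 99.9 for Flag-ADAR1 and 99.4 for the mutant), where gene length is the cause by construction, and double-stranded RNA response genes with at least 3 positions (98.7 for Flag-ADAR1). For the other changes the cause was not tested, beyond the smaller or larger sets that each alternative makes.

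Merging positions closer than 50 bp left 32237 Flag-ADAR1 and 44513 mutant sites, a ratio of 1.38, and merging within 5 bp left 36748 and 52262, a ratio of 1.42. With a score of 10 or more the ratio was 1.14. The shared part of the Flag-ADAR1 list was 60.3% within 100 bp, 43.9% within 5 bp, 20.4% for the upper 50% by score, 11.6% with the mutant list thinned to equal size, 18.6% without the mitochondrial chromosome and unplaced contigs and 20.4% for sites. That of the mutant list was 55.3%, 31.4%, 11.9%, about the same under thinning, 10.7% and 13.9%. Exon labels made up 44.6% of the upper 50% by score for Flag-ADAR1 and 49.1% for the mutant, 32.7% and 32.0% of sites, 39.3% and 40.9% on the placed chromosomes, and 63.7% and 60.9% of the score. Genes with a position numbered 5845 for Flag-ADAR1, 7767 for the mutant and 5025 in both with at least 3 positions, 7467, 7986 and 5147 for the upper 50% by score, 5835, 7124 and 3907 with exon labels, and 5331, 7375 and 4404 with a site of at least 2 positions. The score correlation was 0.593 on the placed chromosomes.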

Other observations

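The tests of run length, of low scores and of Alu shares between the lists, and the comparison of both with a single Alu direction, were chosen only after the results they bear on had been seen, as were all alternatives by Alu class. The other tests below were set down beforehand.

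Messenger RNAs with Alu sequence in their exons carried exonic positions more often than other mRNAs in both lists. Of protein-coding genes, 16103 had no Alu-bearing longest transcript, 1415 had the sense direction, 1466 the antisense direction and 675 both. Among genes with any Flag-ADAR1 position, an exonic one was listed for 45.1% without Alu, 74.0% with sense, 75.2% with antisense and 70.6% with both. For the mutant these were 50.7%, 76.8%, 78.1% and 73.9%. ORAI2, HOOK3 and PLCXD1 were the genes of the class with both directions that had the most exonic positions, named here after their values were seen.

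The mutant list was denser than the Flag-ADAR1 list on these mRNAs. Exonic sites held 2.10 positions on average in Alu-bearing mRNAs for Flag-ADAR1 and 3.04 for the mutant, while in other mRNAs they held 1.88 and 1.97. Alu-bearing mRNAs took 56.9% of the exonic mRNA positions of Flag-ADAR1 and 65.9% of those of the mutant, a ratio of 1.16 (1.13 to 1.19 over resampled genes). Of exonic positions in runs of at least 4, they took 53.4% and 75.4%. Intronic positions in the same genes had a ratio of 1.02 (0.991 to 1.06). Counted as merged sites the exonic ratio was 1.02 (1.00 to 1.05), with a score of 10 or more it was 1.3 (1.2 to 1.43), and without recurring runs it was 1.18 (1.16 to 1.22). The excess thus lay mostly in the width of the runs, and little of it in the number of sites. These intervals compare the 2 lists and not the proteins, with 1 list per construct, and the width of a run also depends on depth and calling.

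The mutant list was longer in general. Low scores are a candidate explanation: with a score of 10 or more the ratio of the lists was 1.14, so most of the excess was below that score. Longer runs cannot be the whole cause, as merged sites still had a ratio of 1.42. Whether the increase was even over all mRNAs stays open: the share of exonic positions in mRNAs with both Alu directions was 1.23 times as large in the mutant list (1.15 to 1.32), but 1.07 times as large (1.01 to 1.14) when counted as merged sites, and with 1 list per construct the spread between lists is unknown. Deeper sequencing, less strict calling and more binding of the mutant all stay open.

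Exonic positions in mRNAs with Alu in both directions were weighed against 5 explanations. Within bins of transcript length and among genes with any position, the odds ratio of an exonic position against mRNAs without Alu was 2.43 for Flag-ADAR1 (2.03 to 2.93) and 2.10 for the mutant (1.73 to 2.56), both with a permutation p of 0.0001, the smallest that the draws can give. Higher coverage of exons and introns alike would raise intronic positions too, but over all genes their odds ratio was 0.805 (0.676 to 0.946) and 0.685 (0.588 to 0.823). For exonic positions it was 2.21 (1.89 to 2.62) and 1.80 (1.55 to 2.11). Intronic positions were not matched on gene span. A higher level of the mature mRNA would raise exonic positions alone, and expression was not measured, so that explanation stays open. Matching on the length of the 3' untranslated region, among genes with any position, left an exonic odds ratio of 2.11 (1.67 to 2.69) and 1.98 (1.63 to 2.47). Reads placed at several Alu copies can give recurring runs. For all exonic runs of at least 4 positions the odds ratio was 4.17 (3.13 to 5.73) and 8.98 (7.31 to 10.7). For those that recur nowhere else it was 2.43 (1.73 to 3.33) and 9.64 (7.97 to 12.3). Only runs with identical spacing and scores counted as recurring, so a run that mixes such reads with others can pass as unique. Such reads may thus account for part of the Flag-ADAR1 value, and the test cannot exclude a larger part in either list. Alu in both directions did not go with exonic positions more often than a single direction did. Against mRNAs with a single direction the odds ratio was 0.780 (0.616 to 0.964, permutation p 0.0397) and 0.809 (0.657 to 0.979, permutation p 0.0772). The search took the longest transcript alone and can miss diverged copies, so some pairs may count as a single direction. Whether binding needs a pair within the mature mRNA therefore cannot be told. Duplexes with Alus in introns or other RNAs are an untested idea. Whether a position lies inside the Alu was not analysed here.

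Some runs of positions had copies elsewhere. Of 2582 Flag-ADAR1 runs of at least 4 positions, 39.2% had a run with the same spacing and the same scores at another place, and of 6552 mutant runs 30.5% did. Scores exchanged between runs gave 16.3% and 12.6%. The most frequent Flag-ADAR1 run was listed 47 times on 20 chromosomes, with 87.8% of its positions intronic, and the most frequent mutant run was listed 32 times. For runs of at least 6 positions the shares were 6.77% and 7.05%, against 0.189% and 0.162% with exchanged scores. Reads placed at several genomic copies are a candidate source. For the genes with the most positions, 19.7% of the Flag-ADAR1 runs recurred, below the share over all runs. For the mutant 27.0% did, which lies between the exchanged scores and all runs. Recurrence fell with run length, to 3.37% for Flag-ADAR1 and 4.23% for the mutant in runs of at least 8 positions. The runs of these genes were not matched to all runs on length, so the comparison cannot decide on this source for either list. The mutant share was uneven over genes: 11 of 15 runs recurred in SNHG14, 8 of 11 in TBC1D8B and 4 of 11 in KCNQ1, but 0 in HFM1, SLCO5A1, TSIX and ZNF793. As only identical spacing and scores counted, a value of 0 does not exclude reads from a similar but diverged copy. Without recurring runs SNHG14 fell from 167 to 119 mutant positions and TBC1D8B from 126 to 86. Of 30 counts for these genes, 29 stayed within 1.5 times without recurring runs, the exception being CROCC in the Flag-ADAR1 list. Counts of genes with no recurring run could not change.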
